A study of Mus musculus with 18 samples.

How the data were processed

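Messenger RNA was measured in 18 libraries of lineage-negative bone marrow progenitors sorted from BALB/c mice, 9 of them from wild-type controls and 9 from animals with a mutated Dnmt1. Per the labels' protocols, cells were sorted straight into lysis buffer without RNA extraction and libraries were made by CEL-Seq2, a method that primes at the poly(A) tail and gives each captured molecule a random tag, the unique molecular identifier (UMI). The labels name 3 populations (HSC, MPP1 and MPP4) and 3 sequencing batches (A, B and C). The column names of the count tables carry 8 ID numbers, 4 per genotype, and the same number occurs in up to 3 populations. In the text each is named after 1 of its libraries: HSC control 1 (990, also MPP4 control 1), HSC control 2 (1156, also MPP1 control 1 and MPP4 control 3), HSC control 3 (1171, also MPP1 control 2 and MPP4 control 4), HSC mutant 1 (996, also MPP4 mutant 1), HSC mutant 2 (1175, also MPP1 mutant 2 and MPP4 mutant 4), HSC mutant 3 (1159, also MPP1 mutant 1 and MPP4 mutant 3), MPP4 control 2 (984) and MPP4 mutant 2 (981). The labels do not say that these numbers are animals, so p-values measure the spread between these libraries, which may be partly technical. Xist and Y-linked transcripts had the same state in all libraries of an ID number.

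The deposited count tables hold whole numbers for 29717 gene symbols per population, and every column could be matched to a sample by its label. The values are estimated counts rather than raw UMI counts: 100% of the 1557 values from 1000 up and below the highest one lay on the grid that a correction for UMI collisions gives with 4096 possible UMIs of 6 bases, compared with 62% of all whole numbers from 1000 to 3000. A deposited value of 1000 on that grid stands for 887 distinct UMIs, an addition of 12.7%. The ceiling of 36909 was reached 7 times in 6 libraries, 4 times by the mitochondrial rRNA mt-Rnr2, in MPP4 control 4 by the gene models Gm10800 and Gm10801, and in MPP4 mutant 2 by Hba-a1, so those values are lower limits. Per the submitters' processing notes, the genome build was mm10 and the tools were R 3.4.0 and DESeq2. The aligner, the counting program and the annotation are not given in the sources used here. The authors' deposited result table for each population holds, per the file headers, DESeq2's mean signal over libraries, the log2 fold change with its standard error, the score of the test, the p-value and the adjusted p-value. The design behind those tables and any shrinkage of the fold changes are not given in the sources used here.

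Estimated counts were used as deposited, with no further rounding needed. Total counts ran from 354642 to 1943562 per library, with a median of 745850.5. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom from 3.455 to 83.389 over genes), so each library was counted as its own sample. A count of 3 was taken as the floor for genes without a count in a group, summed over the group; floors and intervals cover counting error only.

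Each population was fitted by itself with edgeR 4.0.16 in R 4.3.3: TMM normalisation, the default expression filter by genotype (minimum count of 10), a robust quasi-likelihood fit with sequencing batch and genotype as terms (genotype alone in MPP1, all of batch C), and Benjamini-Hochberg adjustment with a threshold of 0.05. Standard errors were derived from the fold change and its F value. The filter left 9147 genes in HSC, 8004 in MPP1 and 9392 in MPP4. Differences of the mutant effect between populations and differences between control populations came from a quasi-likelihood model over all 18 libraries with the ID number as a block, on 10613 genes. Mean values are in CPM, the counts of a gene scaled to a common library total.

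Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count of 2), with the preset correlation of 0.01 between genes and again with an estimated correlation, wherever at least 5 members were tested. The 28 lists cover stem cell identity, lymphoid priming, myeloid progenitors, megakaryocytes, erythroid cells, germline genes kept silent by DNA methylation, imprinted genes, interferon response, MHC class I and class II presentation, S phase, G2/M phase, p53 targets, regulators of apoptosis, the DNA methylation machinery, immediate-early and stress genes, innate NF-kB signalling, ribosomal proteins, mitochondrial transcripts, sex-linked genes, and markers of T cells, B cells, NK and innate lymphoid cells, neutrophils, monocytes and macrophages, dendritic cells, mast cells with basophils and eosinophils, and endothelial or stromal cells.

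The grouping, the tests, the lists and the rule for named genes were fixed before the data were examined. The rule names Dnmt1, Flt3, Il7r, Dntt, Mpo, Gata1 and Mecom where tested, up to 8 genes per direction with the smallest adjusted p and the same sign in every batch, and up to 2 called members of each list. Had fewer than 3 genes passed, it would have named the 3 of each direction with the smallest unadjusted p. It also names genes called in all 3 populations and gives sex-linked genes as values only. For differences between populations it names up to 5 genes per direction, or 2 per direction if none passes, and for the controls 3 members of each of the lists concerned. Some of those members are not reported here. Other genes named here, among them every further called gene, were chosen after their values were seen.

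Tried as alternatives were DESeq2 1.42.0 and limma-voom, RLE normalisation, no filter and a stricter filter of at least 10 counts, a spread shared over all libraries, no batch term, batch C alone, the replicate number as a block, other thresholds, fry in place of camera, and leaving out each library or ID number. A term for the Xist level, an estimated correlation for differences between populations and fits without libraries rich in transcripts of other cell types were added after the data were seen. Same-numbered HSC libraries deviated together from group means (correlations of 0.49, 0.2 and 0.22), as did other batch C pairs (0.24 and 0.12). Number 1 is of batch A, and within batch C same numbers gave −0.02 and −0.2, so no pairing beyond batch was seen. Of genes changed 2-fold and 4-fold in simulated counts, 43.2% and 97.8% were recovered in HSC (8875 genes) and 22.1% and 88.3% in MPP1 (7565). In MPP4 the shares were 22.2% and 97.9% (9162), and for MPP4 minus HSC 15% and 65% (10613). False calls were 12 of 140, 7 of 111, 9 of 124 and 7 of 87.

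Coordinates are those of the GENCODE vM21 annotation of GRCm38, the assembly also called mm10; 83 of 85 named genes had a single locus on the chromosome that the count tables give. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Strand use in counting is not stated, so overlapping and antisense genes cannot be told apart. Genes with near-identical copies are uncertain, among them Xlr3a, Xlr4a, Xlr4b, Hspa1a, Hspa1b, n-R5-8s1, Rps2-ps6 and several Gm models: with 31-base words, Xlr3a shared 55.8%, Xlr4a 84.7%, Xlr4b 56.2%, Hspa1a 63.8% and Hspa1b 67.7% of their sequence with relatives.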

Results

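The study asked what a missense, hypomorphic change in Dnmt1, the enzyme that copies DNA methylation onto newly replicated strands, does to transcription in blood progenitors of the mouse. Control and mutant libraries numbered 3 and 3 in HSC (the label used for haematopoietic stem cells), 2 and 2 in MPP1 and 4 and 4 in MPP4, the last 2 being early and lymphoid-primed multipotent progenitors in common usage. HSC libraries came from batches A and C, MPP1 libraries from batch C, and MPP4 libraries from batches A, B and C, with equal numbers of both genotypes in each batch. Column names carry 8 ID numbers shared between populations, each named here after 1 library. Depth ranged from 354642 counts in HSC control 3 to 1943562 in MPP4 control 2. The genotype field writes the mutants as if they carried a null allele, while the series description speaks of a missense change.

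Dnmt1 transcript itself (chromosome 9, 20907209 to 20959888, GRCm38) was found in every library. In HSC it stood at 212 ± 96.8 CPM in controls and 256.2 ± 112.4 in mutants (SD, n = 3 each), a log2 difference of 0.28 (SE 0.23, edgeR adjusted p = 0.714). In MPP1 the means were 313 ± 4.89 and 276 ± 48.7 CPM (n = 2 each), a difference of −0.18 (SE 0.23, adjusted p = 0.999). In MPP4 they were 326 ± 71.2 and 276 ± 44.8 CPM (n = 4 each), a difference of −0.22 (SE 0.20, adjusted p = 0.901). A missense allele need not alter its own transcript, so this level does not check the genotype labels.

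Control libraries of MPP4 and HSC differed in the genes that give these populations their names. Satb1, a chromatin organiser of lymphoid progenitors, was higher in MPP4 (439 ± 68.0 CPM, n = 4, compared with 43.4 ± 14.6, n = 3; log2 difference 3.31, SE 0.23), as were Irf8, a transcription factor of monocyte and dendritic fate (4.78), the myeloid signalling adaptor Tyrobp (4.35), Wfdc17 (4.44) and Emb (1.80). Il7r, the receptor of the main lymphoid growth factor, stood at 53.9 ± 28.8 CPM in MPP4 controls and had no count in HSC controls. Pdzk1ip1 and Esam, a pair of stem cell markers, were lower in MPP4 by log2 differences of −3.26 and −3.01, as was Mllt3 (−1.93), a regulator of stem cell maintenance. Cell cycle genes were higher in MPP4, among them the proliferation marker Mki67 (1.68), the topoisomerase Top2a (1.64), the spindle protein Nusap1 (1.94), the replication ligase Lig1 (1.26), Uhrf1 (1.44), which brings Dnmt1 to replicating DNA, and Tyms (1.69).

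Megakaryocyte and erythroid regulators were lower in MPP4 than in HSC controls: Nfe2 by −1.14, Gfi1b by −2.03, Apoe by −3.02, Klf1 by −5.14 and Tal1 by −1.45. By list, 23 of 30 stem cell identity genes were lower in MPP4 and none higher, 19 of 32 lymphoid priming genes were higher, and 11 of 29 myeloid genes were higher and 1 lower. Likewise 13 of 17 megakaryocyte genes were lower and 1 higher, and 11 of 29 erythroid genes were lower and 2 higher. Of 53 S phase and 55 G2/M genes, 39 each were higher. With an estimated correlation, camera's adjusted p was 0.0386 for stem cell identity, 0.0472 for lymphoid priming and 0.00579 for G2/M. The calls for myeloid (adjusted p = 0.0754), megakaryocyte (adjusted p = 0.087), erythroid (adjusted p = 0.543) and S phase genes (adjusted p = 0.0681) were lost with an estimated correlation. These were the highest p-values of each list over its 13 alternatives, and the lowest lay between 5.42e-34 for stem cell identity and 1.5e-07 for myeloid genes. The erythroid list was also lost without the ID number of HSC control 1 (adjusted p = 0.334) and in batch C alone (0.225). In all, 1042 of 10613 genes passed, 618 higher and 424 lower in MPP4, compared with 460 without the ID number of HSC control 2 and 658 without that of HSC control 1.

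MPP1 controls lay close to HSC controls, with 25 of 10613 genes past the threshold, 22 higher and 3 lower in MPP1. Myeloid genes were higher in MPP1: the neutrophil protease Prtn3 (423 ± 38.6 CPM, n = 2, compared with 146 ± 84.9, n = 3; log2 difference 2.21, SE 0.29), the myeloid cell cycle regulator Ms4a3 (4.25) and Tyrobp (3.70). Cell cycle genes that passed were Cdk1 (1.07), the kinase that drives entry into mitosis, Nusap1 (1.34), Ube2c (1.07), which marks mitotic proteins for destruction, and thymidine kinase Tk1 (1.37). All of these calls but that of Prtn3 rested on single ID numbers, in edgeR's adjusted p. Ms4a3 was lost without that of HSC control 2 (0.631, range over alternatives 1.93e-07 to 0.631) and Tyrobp without that of HSC mutant 3 (0.0588, range 9.17e-10 to 0.12). Without those of HSC control 2, control 3 and control 1 in turn, Tk1 stood at 0.182, 0.4 and 0.213 (range 0.00238 to 0.4), Cdk1 at 0.557, 0.124 and 0.129 (range 0.00483 to 0.557) and Nusap1 at 0.33, 0.219 and 0.106 (range 0.000787 to 0.33). Ube2c stood at 0.382, 0.655 and 0.0538 without those of HSC control 2, control 3 and mutant 2 (range 0.00556 to 0.656). The myeloid and G2/M lists were higher in MPP1 with an estimated correlation (camera adjusted p = 0.0358 and 0.0106). The lower stem cell identity list (median −0.34, adjusted p = 0.00028) and the higher S phase list (median 0.62, adjusted p = 2.73e-17) had adjusted p = 0.382 and 0.194 with an estimated correlation. These were the highest p-values of those 4 lists over their alternatives, and the lowest were 1.69e-21, 1.82e-32, 2.47e-05 and 2.34e-23 in the order given. Stem cell identity was also lost without the ID number of HSC control 3 (adjusted p = 0.214). Lymphoid priming, megakaryocyte and erythroid lists did not pass (adjusted p = 0.802, 0.164 and 0.124), though the erythroid list passed without that number (5.18e-06) and ranged up to 0.858, and the megakaryocyte list passed in batch C alone (0.0256) and ranged up to 0.849. The direction of lymphoid priming turned without the ID number of HSC control 1 (0.29) or HSC control 3 (0.947) and in batch C alone (0.204, range up to 0.954).

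Members of those lists that did not pass between MPP1 and HSC included Pdzk1ip1 (−0.68), Mllt3 (−0.43), Egr1 (−0.57), Wfdc17 (−2.40), Bcl11a (−0.36), Fli1 (−0.64), Vwf (−1.21), Gfi1b (−0.71), Car1 (−5.09), Klf1 (−2.28), Usp1 (0.89), Tyms (1.27) and Slc4a1 (5.12), an erythrocyte membrane protein. Slc4a1 differed by −2.73 without the ID number of MPP1 control 2, and passed without that of HSC control 1 (7.74, adjusted p = 0.000232) or HSC mutant 1 (5.13, adjusted p = 0.0246) and in batch C alone (7.54, adjusted p = 0.000751), with a range of 1.82e-07 to 1 over alternatives. Tyms passed with no filter on low counts (adjusted p = 0.0304, range up to 0.52). Car1, a carbonic anhydrase of red cells, passed without that of MPP1 control 2 (−9.30, adjusted p = 4.8e-09) or HSC mutant 1 (−5.08, adjusted p = 0.0438), with a range of 5.17e-18 to 1. MPP1 control 1 had no count of Slc4a1 or Car1, so these sizes are fitted values and no bounds. MPP1 control 2 held 33502 CPM of erythroid and 9364 CPM of neutrophil transcripts. The count of 25 was 16 without the ID number of HSC control 2, 40 without that of HSC mutant 1 and 3 with batch in place of the ID number.

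In HSC, germline genes and immediate-early genes rose in mutants. Slc25a31, an ADP/ATP carrier of the male germ line (chromosome 3, 40708855 to 40726096), had no count in the control libraries and 42, 44 and 17 counts in the mutants, at least 24.6-fold higher (adjusted p = 4.41e-05). The X-linked gene 3830403N18Rik (56136572 to 56153498), which is not in the germline list, had no count in controls either and was at least 17.7-fold higher (adjusted p = 0.000297). Xlr3a, of an X-linked lymphocyte-regulated family with meiotic members, had 2 counts in controls and 79 in mutants, a pooled ratio of 28.3 (95% counting interval 7.59 to 238). Fos, a subunit of the AP-1 transcription factor induced within minutes of a stimulus (chromosome 12, 85473890 to 85477273), rose from 141 ± 69.3 to 479 ± 63.4 CPM (SD, n = 3 each), a log2 change of 1.84 (SE 0.26). The calls of Fos and Hspa1b were lost in 1 alternative each, Fos without the batch term (adjusted p = 0.221, range over alternatives 4.57e-10 to 0.221) and the heat-shock gene Hspa1b with a spread shared over all libraries (0.212, range 4.57e-10 to 0.212).

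All 3 tested germline genes rose in HSC mutants (Slc25a31, Xlr3a and Xlr4b, the last by 2.02, SE 0.37), and all 3 passed adjusted over the list alone. Their median change was 4.71, or 4.62 with the gene at 0 set at its bound, and 3 members were too few for camera. Slc25a31 and Xlr3a passed the count filter through mutants alone, so they could hardly have fallen. Of the 26 immediate-early and stress genes, 7 rose (9 adjusted over the list alone): Fos, Fosb (1.84, SE 0.29) and Jun (1.45, SE 0.26), which pair into AP-1, the zinc-finger factors Egr1 (1.36), Klf2 (1.45) and Klf4 (2.06), and Hspa1b, the inducible heat-shock chaperone, with 3 counts in controls (pooled ratio 26.5, 95% counting interval 8.85 to 131). The list was higher with camera (adjusted p = 1.41e-07), a call lost with an estimated correlation (adjusted p = 0.343). Egr1 lost its call without control 1 (adjusted p = 0.373), control 3 (0.0822), mutant 1 (0.453) or mutant 3 (0.112), with a range of 3.77e-05 to 0.965 over alternatives.

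**Figure D1:**
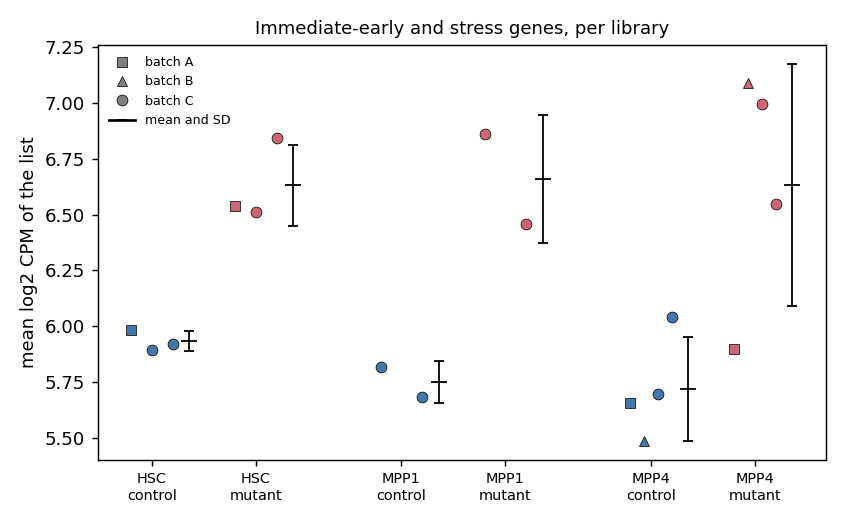
Mean log2 CPM of the immediate-early and stress list per library, with marker shapes for batches A, B and C, blue for controls and red for mutants, and the mean with SD beside each group. Mutant means were 6.63 ± 0.18 in HSC, 6.66 ± 0.29 in MPP1 and 6.63 ± 0.54 in MPP4, compared with 5.93 ± 0.05, 5.75 ± 0.10 and 5.72 ± 0.23 in controls.

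Proliferation genes stood higher in HSC mutants as lists. Of 53 S phase genes, 52 were higher (median 0.59), but Tyms, the thymidylate synthase of DNA synthesis, was alone in passing (1.53, SE 0.31, and 5 genes adjusted over the list alone). Of 53 G2/M genes, 48 were higher (median 0.65) and 17 passed adjusted over the list alone, while over all genes no member passed in edgeR and 31 had an unadjusted p under 0.05. With the replicate number as a block, Tk1 of the S phase list (adjusted p = 0.0441), Mki67 of the G2/M list (0.0233) and Rpl29 of the ribosomal list (0.0196) passed in edgeR as well. Tyms lost its call without control 1 (adjusted p = 0.0863), control 2 (0.0799), mutant 1 (0.085) or mutant 2 (0.129), with a range of 0.00122 to 0.359 over alternatives. Camera's adjusted p was 5.14e-14 for S phase and 2.47e-14 for G2/M, and both calls were lost with an estimated correlation (adjusted p = 0.505 and 0.343). Ribosomal protein genes were higher in 76 of 77 (median 0.33; adjusted p = 8.64e-09, and adjusted p = 0.505 with an estimated correlation). For all 7 lists called in HSC the p-value with an estimated correlation was the highest over 16 alternatives, and the lowest lay between 7.04e-18 for G2/M and 0.000248 for imprinted genes.

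Erythroid genes were higher as a list in HSC mutants (median 0.99; adjusted p = 3.88e-05, and adjusted p = 0.505 with an estimated correlation), with 1 of 20 members past the threshold and 3 adjusted over the list alone. That member was Mfsd2b, an exporter of sphingosine-1-phosphate in red cells (1.70, SE 0.37, adjusted p = 0.0343), which was lost without control 1 (0.79), control 3 (0.0703), mutant 1 (0.93) or mutant 2 (0.425), with a range of 0.000295 to 0.965. HSC mutant 1 held 15992 CPM of erythroid transcripts where the other HSC libraries held 1923 to 2376, and the list's adjusted p was 0.235 without that library and 0.494 without HSC control 1, which held 39279 CPM of B cell transcripts. Stem cell identity genes were lower (median −0.30 over 30; adjusted p = 0.000387, and adjusted p = 0.505 with an estimated correlation), though the only member to pass, Egr1, rose. Without control 1 or mutant 1 the list's adjusted p was 0.293 or 0.286. Imprinted genes, expressed from the copy of a single parent under control of DNA methylation, were lower in 19 of 23 (median −0.36; adjusted p = 0.00111, and adjusted p = 0.343 with an estimated correlation), with no member passing in edgeR and 1 at an unadjusted p under 0.05. Lymphoid priming genes had a median of −0.20 over 19 and did not pass (adjusted p = 0.0504). They passed without control 2 (0.0298), control 3 (0.0327), mutant 2 (0.0497) or mutant 3 (0.00601) and with the replicate number as a block (0.0435), the stricter filter (0.0216) or the Xist level as a term (0.0415), over a range of 0.00601 to 0.505. Their adjusted p was 0.332 without control 1, 0.286 without mutant 1 and 0.325 in batch C alone.

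Further genes that rose in HSC mutants were Gpx4, which reduces lipid peroxides (1.97, SE 0.30), the splicing regulator Hnrnpf (2.03, SE 0.33), the glutamate transporter Slc17a8 (2.15), the growth factor Tgfb1 (1.64), the calcium-binding protein S100a6 (1.31), the ribosomal RNA copy n-R5-8s1 (2.49) and the pseudogene Rps2-ps6 (2.09). In edgeR's adjusted p, Gpx4 and Hnrnpf were lost without the batch term (0.965 each), and Hnrnpf (0.404) and n-R5-8s1 (0.21) with a shared spread. Over alternatives it ranged from 2.07e-08 to 0.965 for Gpx4, from 4.76e-08 to 0.965 for Hnrnpf and from 9.15e-09 to 0.21 for n-R5-8s1. Nrk, a protein kinase (−2.12, SE 0.47), and the gene model Gm38082 (−1.74, SE 0.38) fell, each with adjusted p = 0.0389. Nrk was lost without control 1 (0.345), control 2 (0.167), mutant 1 (0.242) or mutant 2 (0.406), with a range of 0.0038 to 0.948. Gm38082 was lost without control 1 (0.227), control 3 (0.251), mutant 1 (0.254), mutant 2 (0.0902) or mutant 3 (0.0805), with a range of 0.000514 to 0.965. Gata1, the master regulator of red cells and platelets, did not pass (1.46, SE 0.33, adjusted p = 0.0513) but passed without control 2 (0.0263), without mutant 3 (0.0022), with no filter (0.000622), with the stricter filter (0.0445) and with the replicate number as a block (0.00741), over a range of 0.000622 to 1. The lymphoid receptor Flt3 (−0.42, adjusted p = 0.725), the stem cell factor Mecom (−0.62, adjusted p = 0.434) and myeloperoxidase Mpo (−0.83, adjusted p = 0.95) did not pass, and the sign of Mpo turned without control 3 (2.17), mutant 2 (0.44) or mutant 3 (0.10).

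In total, 22 of 9147 genes changed in HSC, 20 up and 2 down, all with the same sign in batches A and C. Fos differed by 1.11 in batch A and 2.20 in batch C (log2 CPM). With the replicate number as a block the count was 40, all 22 among them, and 9 lists passed with camera in place of 7, the further ones being lymphoid priming and megakaryocyte genes (adjusted p = 0.0435 each). In batch C alone, which leaves out control 1 and mutant 1, the count was 18, of which 12 were among the 22. It was 14 with DESeq2, 5 without the batch term and 9 with a shared spread. With 1 library left out it was 53 without control 2, 39 without control 3, 13 without mutant 2 and 83 without mutant 3.

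In MPP1, immediate-early genes rose in mutants and a kinetochore gene fell. Fos rose from 87.3 ± 21.6 to 592 ± 228 CPM (SD, n = 2 each; log2 change 2.78, SE 0.29, adjusted p = 1.35e-05) and Fosb from 80.4 ± 4.93 to 371 ± 125 CPM (2.19, SE 0.27; adjusted p = 1 with a shared spread, range over alternatives 5.43e-13 to 1). Klf4, a zinc-finger factor of quiescence and myeloid fate, rose by 3.48 (SE 0.52; adjusted p = 0.151 without mutant 1, 0.122 with limma-voom and 1 with a shared spread, range 4.58e-08 to 1), Klf6 by 1.83 and Klf2 by 1.99. Spc24, a component of the complex that ties chromosomes to the spindle, was the only gene that fell, by 2.66 on the log2 scale (adjusted p = 0.00115), a call lost with limma-voom (adjusted p = 0.201, range 1.52e-07 to 0.201). Xlr3a had no count in controls and 10 and 26 counts in mutants, at least 26.7-fold higher (adjusted p = 0.000905).

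The gene 4930447C04Rik, which encodes a protein of meiotic chromosome pairing, rose by 3.28 (SE 0.51) in MPP1 mutants, Slc17a8 by 3.54 (SE 0.49) and Hnrnpf by 2.05 (SE 0.35). With a shared spread and with limma-voom in turn, the adjusted p was 0.0603 and 0.0553 for 4930447C04Rik (range 1.13e-06 to 0.0603) and 0.131 and 0.0552 for Slc17a8 (range 2.39e-08 to 0.131). Among mitochondrial transcripts 1 of 12 rose, the methionine tRNA mt-Tm (1.62, SE 0.27). The gene models Gm10801, Gm17535, Gm21738, Gm10717, Gm26870 and Gm10718, which hold satellite-like repeat sequence, rose by 1.84 to 2.45, and Gm38197 rose by 1.53. With a shared spread mt-Tm and Gm17535 each had adjusted p = 1 (ranges 1.02e-06 to 1 and 9.4e-12 to 1). The summed level of 13 such models, a set chosen after the data were seen, was 34538 and 18863 CPM in the MPP1 controls, 83153 and 105812 in the MPP1 mutants, and 713 to 302797 over all 18 libraries. Of the 2 tested germline genes 1 rose and both rose adjusted over the list alone (median 4.49, or 2.94 with the gene at 0 set at its bound). Xlr3a, without a count in controls, passed the count filter through mutants alone, so it could not have fallen.

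Of 24 immediate-early and stress genes in MPP1, 5 rose over all genes, and 11 rose and 3 fell adjusted over the list alone (camera adjusted p = 8.18e-09, and adjusted p = 0.72 with an estimated correlation). S phase genes (median −0.21 over 52; adjusted p = 0.000621), G2/M genes (median −0.23 over 51; adjusted p = 0.00945) and myeloid progenitor genes (median −0.38 over 24; adjusted p = 0.0432) were lower as lists with no member passing in edgeR (4, 4 and 1 at an unadjusted p under 0.05), and each had adjusted p = 0.72 with an estimated correlation. Ribosomal protein genes (median 0.13 over 77; adjusted p = 0.0242) and p53 targets (median 0.21 over 18; adjusted p = 0.0388) were higher with no member passing, and had adjusted p = 0.752 and 0.72 with an estimated correlation. For all 6 lists the p-value with an estimated correlation was the highest over 11 alternatives, and the lowest lay between 5.15e-11 for immediate-early genes and 0.0259 for p53 targets. Neutrophil transcripts stood at 9364 CPM in control 2 and at 295 to 334 CPM in the other MPP1 libraries. Calls of 5 of these lists rested on single libraries. Without mutant 1 the adjusted p of S phase, G2/M and ribosomal genes was 0.505 in each case, that of p53 targets 0.419 and that of myeloid genes 0.196. Without control 1 it was 0.232 for myeloid genes, 0.062 for p53 targets and 0.272 for ribosomal genes, whose direction turned. Without control 2 it was 0.126 for S phase genes and 0.277 for G2/M genes and p53 targets. The number of lists that passed was 6, compared with 2 without mutant 1 and 12 without mutant 2. The immediate-early list passed with each library left out.

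Flt3 (−0.24), Mpo (−0.48) and Mecom (0.47) did not pass in MPP1 (each with adjusted p = 0.999), and Flt3 turned to 0.45 without mutant 2. In total 18 of 8004 genes changed, 17 up and 1 down, all within batch C. With a single library left in a group the fit assumes that it varies like the other group: 75 genes passed without control 1, 54 without control 2 and 32 without mutant 2, of which 16, 18 and 13 were among the 18. With a spread shared over all 18 libraries 4 genes passed, and 41 with no filter on low counts. With 2 libraries against 2 an exact permutation test of a single value cannot give a two-sided p below 0.333.

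In MPP4, germline genes, AP-1 genes and G2/M genes stood higher in mutants. Slc25a31 had no count in the 4 control libraries and 25, 6, 5 and 63 counts in the mutants, at least 62.6-fold higher (adjusted p = 0.0169). 3830403N18Rik rose from 1.34 ± 1.92 to 28.5 ± 16.0 CPM (SD, n = 4 each; log2 change 5.05, SE 0.74) and Xlr4a from 1.11 ± 1.70 to 16.7 ± 3.36 CPM (3.62, SE 0.66). Fos rose from 99.0 ± 21.9 to 430 ± 168 CPM (2.06, SE 0.24, adjusted p = 0.000914) and Jun from 153 ± 38.1 to 521 ± 253 CPM (1.72, SE 0.27). Stag3, a cohesin subunit of meiotic chromosomes (chromosome 5, 138280240 to 138312393), rose from 14.97 ± 7.66 to 51.25 ± 22.6 CPM (adjusted p = 0.0169), the transporter Slc16a11 by 2.21 (SE 0.36) and Tifab, an inhibitor of innate immune signalling, by 1.95 (SE 0.32). Fos kept its call in MPP4 under all 19 alternatives (adjusted p at most 0.0257), whereas the other called genes lost theirs with single libraries left out. Without control 1, control 3 and mutant 1 in turn, edgeR's adjusted p was 0.0721, 0.0773 and 0.0792 for Slc25a31 (range over alternatives 4.13e-15 to 0.0792) and 0.0614, 0.0773 and 0.139 for 3830403N18Rik (range 3.34e-11 to 0.139). It was 0.0947, 0.101 and 0.139 for Stag3 (range 2e-05 to 0.623) and 0.127, 0.115 and 0.139 for Tifab (range 8.23e-08 to 0.143), which was also lost without mutant 3 (0.0674). For Jun it was 0.0614, 0.0773 and 0.0965 (range 9.92e-08 to 0.143), and Jun was also lost without control 4 (0.0756) and without control 4 and mutant 2 together (0.0814). Slc16a11 was lost without control 3 (0.0773), mutant 1 (0.0731) or control 4 and mutant 2 together (0.0547), with a range of 3.69e-06 to 0.226. Xlr4a, which shares most of its sequence with relatives, was lost without control 1 (0.0614), control 3 (0.174), control 4 (0.0802), mutant 1 (0.135), mutant 2 (0.0683), mutant 3 (0.0985) or mutant 4 (0.156), with a range of 0.000373 to 0.174.

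Of 5 tested germline genes in MPP4, 2 rose, and all 5 rose adjusted over the list alone (median 3.09, also with Slc25a31 at its bound; camera adjusted p = 2.76e-11, and adjusted p = 0.157 with an estimated correlation). Of 55 G2/M genes, 53 were higher (median 0.60) and 28 passed adjusted over the list alone, while over all genes no member passed in edgeR and 33 had an unadjusted p under 0.05 (camera adjusted p = 5.97e-23, and adjusted p = 0.157 with an estimated correlation). These 2 lists also passed fry's directional test (adjusted p = 0.0359 each), which asks whether a list moves on balance and not whether it moves more than other genes. Of 25 immediate-early and stress genes 2 rose, and 9 adjusted over the list alone (median 0.98; adjusted p = 6.21e-10, and adjusted p = 0.247 with an estimated correlation).

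**Figure D2:**
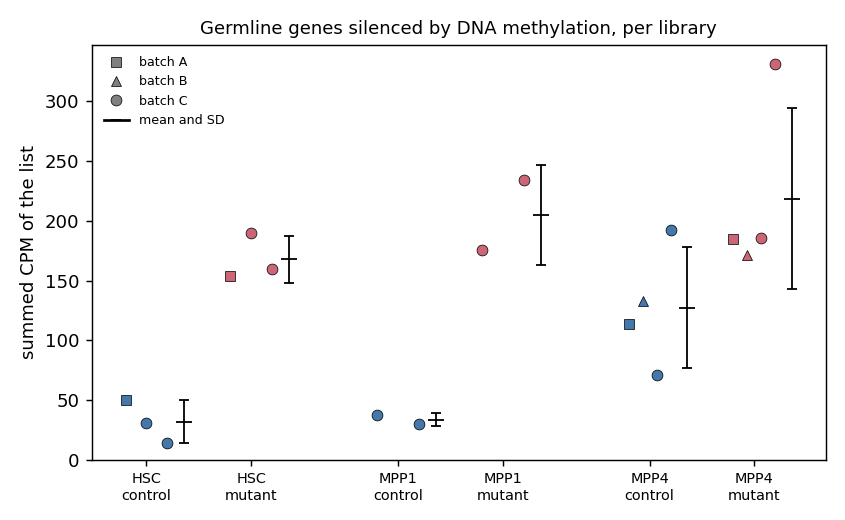
Summed CPM per library of the germline genes kept silent by DNA methylation, with marker shapes for batches, blue for controls, red for mutants, and the mean with SD beside each group. MPP4 control 4, at 192.5 CPM, lies above MPP4 mutants 1, 2 and 3 at 184.7, 171.5 and 185.6 CPM, while in HSC and MPP1 no control reaches a mutant.

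**Figure D3:**
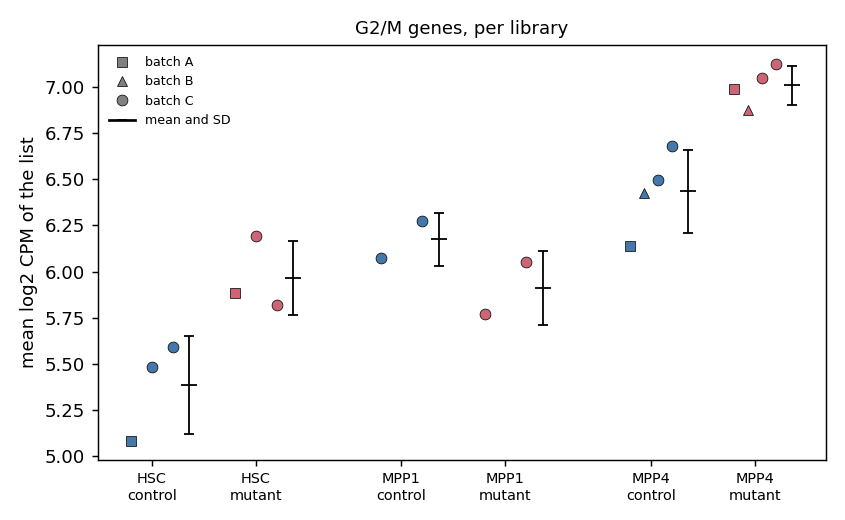
Mean log2 CPM of the G2/M list per library, with marker shapes for batches, blue for controls, red for mutants, and the mean with SD beside each group. Mutant and control means were 5.97 ± 0.20 and 5.39 ± 0.27 in HSC, 5.91 ± 0.20 and 6.17 ± 0.14 in MPP1, and 7.01 ± 0.11 and 6.43 ± 0.22 in MPP4.

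Ribosomal protein genes were higher in MPP4 mutants in 77 of 77 (median 0.29; adjusted p = 6.25e-10, and adjusted p = 0.825 with an estimated correlation), with adjusted p = 0.136 without control 1 and 0.124 without mutant 1 and a range of 5.53e-16 to 0.855 over alternatives. MHC class I genes, which present peptides to T cells, were higher with no member passing and 3 at an unadjusted p under 0.05 in edgeR (median 0.21 over 21; adjusted p = 0.0468, and adjusted p = 0.284 with an estimated correlation), a call also lost without control 1 (0.136), control 3 (0.189), mutant 1 (0.129), mutant 3 (0.064) or mutant 4 (0.153) and ranging from 0.000437 to 0.284. For the germline, G2/M and immediate-early lists the p-value with an estimated correlation was the highest over alternatives, and the lowest were 5.96e-14, 1.9e-33 and 2.79e-17.

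Lymphoid genes did not pass in MPP4, the lymphoid-primed population. Il7r was lower without passing (−1.55, SE 0.62, adjusted p = 0.678; −1.50, −5.09 and −0.72 in batches A, B and C), though it passed with no filter on low counts (0.005, range 0.005 to 1). Dntt, which adds nucleotides at antigen receptor joints, differed by −0.08 (SE 0.38, adjusted p = 0.984), and Flt3 by −0.01 (SE 0.23, adjusted p = 0.998). The sign turned for Flt3 without control 1 (0.01), control 2 (0.20), mutant 1 (0.01) or mutant 2 (0.20), and for Dntt without control 2 (0.41) or mutant 2 (0.41). The lymphoid priming list had a median of −0.06 over 31 genes (adjusted p = 0.31). It passed without control 1 (0.0438) or mutant 3 (0.0218), and its direction turned without control 2 (0.878) or mutant 2 (0.808), the ends of its range over alternatives being 0.0218 and 0.878. Mpo (−0.46, adjusted p = 0.918) and Mecom (0.12, adjusted p = 0.962) did not pass either, and Mecom turned without control 2 (−0.0041), control 3 (−0.05) or mutant 3 (−0.17).

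Erythroid and neutrophil transcripts of MPP4 libraries were concentrated in mutant 2, with 192529 and 36564 CPM, and control 4, with 30597 and 4065 CPM. In total 8 of 9392 genes changed in MPP4, all upward and with the same sign in batches A, B and C. The count was 5 without control 1, 20 without control 2, 1 without control 3, 2 without mutant 1, 19 without mutant 2 and 17 without mutant 4. It was 21 without control 4 and mutant 2 together, 3 without the batch term and 28 with DESeq2. It was 88 with no filter on low counts and 17 with a spread shared over all libraries.

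Fos was the only gene called in all 3 populations. HSC and MPP1 shared 7 called genes that rose (Fos, Fosb, Hnrnpf, Klf2, Klf4, Slc17a8 and Xlr3a), where independent lists would share 0.03. HSC and MPP4 shared 4 (Fos, Jun, Slc25a31 and 3830403N18Rik; 0.0078), and MPP1 and MPP4 shared Fos (0.0058). The populations share ID numbers, so part of this overlap may come from what libraries of the same ID number share. Of the 18 genes called in HSC and tested in MPP4, 18 had the same sign there, as did 14 of 16 tested in MPP1. Of the genes called in MPP1, 10 of 18 tested in HSC and 10 of 16 tested in MPP4 had the same sign there. Of those called in MPP4, 4 of 4 tested in HSC and 3 of 3 tested in MPP1 did.

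The mutant effect differed between MPP4 and HSC for 3 genes: the neutrophil genes Ly6g (log2 difference −10.97, SE 1.90, adjusted p = 0.0266) and Mmp9 (−10.95, SE 1.94, adjusted p = 0.0266), and Slc4a1 (−12.00, SE 1.78, adjusted p = 0.032). These are fitted values over libraries partly without a count, and no bounds: with batch in place of the ID number they were −1.07, −1.69 and −4.75, with the replicate number as a block −1.26, −1.85 and −2.80, and with DESeq2 −1.66, −1.61 and −6.26 (adjusted p = 1 for each). The transcripts mark mature neutrophils and red cells, and Ly6g had no CPM outside HSC mutant 1 (11.6), MPP1 control 2 (80.5), MPP4 control 4 (34.8) and MPP4 mutant 2 (443.5). The calls were lost without MPP4 mutant 2, the only library of its ID number, which the ID term absorbs: Ly6g, Mmp9 and Slc4a1 still differed by −10.94, −10.93 and −11.92, with SEs of 2.68, 2.62 and 2.0 (edgeR adjusted p = 0.418, 0.418 and 0.0959). The unadjusted p of Slc4a1 was 9.05e-06 with that library and 8.68e-06 without it. In edgeR's adjusted p, Ly6g and Mmp9 were also lost without the ID number of HSC mutant 1 (−6.05 and −5.94, adjusted p = 1) or HSC control 3 (−5.08 and −5.18, adjusted p = 1), with ranges of 6.48e-05 to 1 and 0.00016 to 1. Slc4a1 was also lost without that of HSC mutant 1 (0.857), HSC control 3 (1), HSC control 2 (0.383), HSC mutant 3 (0.062) or HSC mutant 2 (0.0599), with a range of 1.4e-15 to 1. The count was 0 without the ID number of MPP4 mutant 2, 6 without that of HSC control 2 and 10 without that of HSC control 1. It was 0 with batch in place of the ID number and 0 with the replicate number as a block. DESeq2 called 1 other gene, and 9 genes passed without the 5 libraries richest in such transcripts. Unadjusted p under 0.05 was reached by 412 genes, where 531 were to be expected by chance.

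G2/M genes moved apart between populations. Their mutant effect was lower in MPP1 than in HSC (median −0.83 over 55 genes; camera adjusted p = 5.15e-15, and adjusted p = 0.029 with an estimated correlation) and higher in MPP4 than in MPP1 (median 0.65; adjusted p = 2.78e-16, and adjusted p = 0.0234 with an estimated correlation). Without the ID number of HSC control 2 these 2 estimated-correlation p-values were 0.351 and 0.364, and without that of HSC mutant 3 they were 0.194 and 0.2. They were 0.249 and 0.156 without that of HSC control 3, 0.0814 and 0.0847 without that of HSC control 1, and 0.0919 and 0.0823 without that of HSC mutant 1. No single gene passed in either comparison in edgeR with the count filter or in DESeq2, with 505 and 466 genes at an unadjusted p under 0.05 in edgeR. For MPP1 minus HSC, edgeR called 2810417H13Rik and E2f2 with no filter on low counts (adjusted p = 0.0204 each, the lowest over alternatives, the highest being 1 and 0.997) and 1 gene in batch C alone. Without the 5 libraries richest in transcripts of other cells 2 genes passed for MPP1 minus HSC and 8 for MPP4 minus MPP1. Without the ID number of HSC control 2, 4 genes passed for MPP4 minus MPP1. The genes with the smallest p, none of which passed with the filter and all libraries, were Gm38197 (1.82), St8sia4 (1.43), 2810417H13Rik (−1.61) and E2f2 (−3.64) for MPP1 minus HSC, and Ube2c (1.43), Ccnb2 (1.56), Zfp112 (−8.59) and Myom1 (−3.86) for MPP4 minus MPP1. The last 2 and E2f2 had no count in some of the libraries, so their sizes are fitted values and no bounds.

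The authors' deposited tables call 8 genes in HSC, 7 in MPP1 and 13 in MPP4 at an adjusted p of at most 0.05, of which Stag3 and Xlr4a in MPP4 stand at 0.05 after rounding. All of those in HSC and MPP1 were also called here, and 7 of those in MPP4, where 10 were tested here. In the authors' deposited table for MPP4 the further calls are the heat-shock genes Hspa1a (2.28) and Cryab (1.98), the immediate-early genes Fosb (1.89) and Egr1 (1.72), the mitotic gene Ube2c (1.25) and Clec10a (1.76), on the authors' log2 scale. Fosb, Egr1 and Ube2c were tested here without passing, and Hspa1a, Cryab and Clec10a did not reach the count filter. Fold changes in those tables had a correlation of 0.94, 0.90 and 0.93 with the ones here, across genes, which are not independent replicates.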

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

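Chosen only after the result was seen were all 3 tests on immediate-early genes, the permutations within batches, the estimated correlation for differences between populations, the batch C values, the differences of the list's mean and the estimated-correlation p-values on G2/M genes, the correlation and the comparison across populations for satellite-like models, and the counting of splits over those ID numbers that carry weight.

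The immediate-early and stress list stood higher in mutants of all 3 populations, by 0.93 (mean log2 CPM) between 4 mutant and 4 control ID numbers. The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 can give (0.0381 adjusted over 8 such tests). That permutation ignores batch, and within batches the exact p was 0.0833, the smallest that 24 arrangements can give. Sex alone is argued against: in each Xist state of batch C mutants were higher in 6 of 6 pairs, by 0.51 to 1.3. The pairs repeat 4 ID numbers. Admixed red cells or neutrophils stay open: without HSC control 1, HSC mutant 1, MPP1 control 2, MPP4 control 4 and MPP4 mutant 2, the 5 libraries richest in transcripts of other cells, the mutant minus control differences of 0.70, 0.91 and 0.91 in HSC, MPP1 and MPP4 (SE 0.26, 0.32 and 0.22) became 0.77, 0.84 and 0.87 (SE 0.33, 0.41 and 0.27), and the ratios to the SE of 2.32 in HSC and 2.07 in MPP1, with 1 control left, lay under the two-sided 0.05 t quantile of 2.36, while MPP4 had 3.21. Handling of the cells that differed between genotypes may also raise such genes and cannot be told apart from the mutation, because both would part the same ID numbers, and the mutation itself stays open and untested.

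G2/M genes differed in mutant effect between populations, by a median of −0.83 for MPP1 minus HSC and 0.65 for MPP4 minus MPP1. A single MPP1 library as the whole difference is argued against, since with 1 ID number left out the differences of the list's mean ran from −0.78 to −0.71 and from 0.75 to 0.84 (SE at most 0.12), with a camera adjusted p of at most 1.02e-08 for the latter. Admixed cells stay open: without the 5 libraries the differences were −0.70 and 0.76 (SE 0.17 each), compared with −0.73 and 0.77 (SE 0.09 each) over all 18, but with 2 residual degrees of freedom the two-sided 0.05 t quantile is 4.3 standard errors, and camera's adjusted p of at most 8.89e-10, which met the bound set beforehand, takes genes as nearly independent. With an estimated correlation the adjusted p-values of 0.029 and 0.0234 became 0.679 and 0.72 without the 5 libraries, and 0.351 and 0.364, 0.249 and 0.156, 0.0814 and 0.0847, 0.194 and 0.2, and 0.0919 and 0.0823 without the ID numbers of HSC control 2, control 3, control 1, mutant 3 and mutant 1, fits with fewer libraries and a larger SE. A state of the animals shared by all their cells, several MPP1 libraries together and a real difference between the populations stay open, since the batch C differences of −0.27 in MPP1 (2 libraries against 2), 0.47 in HSC and 0.5 in MPP4 (SE 0.16 each) are part of the pattern itself.

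Satellite-like gene models, of which 6 rose in MPP1 mutants, varied widely between libraries of every population. Their level ran with the number of genes found at a fixed depth over 18 libraries (Spearman 0.85, permutation p = 2e-05; Pearson 0.78, p = 3e-05; without the 2 farthest libraries Pearson 0.73, p = 0.0013), and Spearman's value was 0.9 in controls, 0.72 in mutants and 0.82 in batch C, batches A and B holding too few libraries (4 and 2). Background reads that vary between libraries may account for this pattern. Reads shared between near-identical copies stay open, with a median of 45.75% of 31-base words shared with another called model (21.6% to 93.3%). Loss of DNA methylation in every mutant population stays open as well: mutants differed from controls by −0.39 (log10 CPM) in HSC, 0.57 in MPP1 and −0.16 in MPP4, with exact two-sided permutation p = 0.4, 0.333 and 0.886.

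Other splits of the HSC libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 22 genes and 7 lists and the highest other 25 genes and 11 lists, with 2 splits reaching each real count. The count of 22 genes was 53 without control 2, 39 without control 3, 13 without mutant 2 and 83 without mutant 3. Of the splits that part all 3 same-numbered pairs, as the real one does, 4 gave 2 to 25 genes and 3 to 7 lists, while the 6 that part 1 pair gave 0 or 1 genes and 1 to 11 lists. The split with 25 genes sets control 1, control 2 and mutant 3 against the rest and follows the Xist state within batch C. With the Xist level as a term the real split gave 15 genes.

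Chance is not excluded for the MPP4 counts. Of 35 splits (34 fitted), 3 reached the real 8 genes and 24 the real 5 lists. The highest others were 40 genes and 10 lists. The split with 40 genes (controls 1 and 4, mutants 1 and 2) points to a structure other than genotype. It and one with 10 genes join control 4 and mutant 2, rich in erythroid and neutrophil transcripts. Others that do gave 0 to 5. The 8 genes were 5, 20 and 1 without controls 1, 2 and 3 and 2, 19 and 17 without mutants 1, 2 and 4, and the 5 lists were 9 without control 4.

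For the difference of the mutant effect, 10 splits of the 6 ID numbers found in both HSC and MPP4 are too few for a share under 0.05. The mutant effect differed between MPP4 and HSC for 3 genes and 6 lists, with 37 genes and 12 lists as the highest others, and 7 and 5 splits reached the real counts. The 37 genes, with the ID numbers of HSC controls 1 and 2 and mutant 1 together, point to a structure of the samples. The 3 genes were 0 without the ID number of MPP4 mutant 2, which hardly moved the differences themselves, 6 without that of HSC control 2 and 10 without that of HSC control 1. Controls of MPP4 and HSC differed in 1042 genes and 12 lists, with 4 genes and 14 lists as the highest others, and 1 and 5 splits reached the real counts. The 1042 genes were 460 without the ID number of HSC control 2 and 658 without that of HSC control 1.

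Of 85 tests, 9 found a library far from the other 3 of its group. Chance gives 4.2 of independent tests, but these share libraries. In MPP4 controls the gap to the nearest library, over the group's range, was 0.916 for stem cell identity in control 2, 0.898 for the DNA methylation machinery in control 3, and 0.908 for erythroid and 0.95 for neutrophil genes in control 4. Among MPP4 mutants it was 0.902 for erythroid, 0.946 for neutrophil, 0.863 for monocyte and 0.865 for innate NF-kB genes in mutant 2, and 0.861 for B cell genes in mutant 3.

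Between MPP4 and HSC the mutant effect differed by test for Ly6g (−10.97), Mmp9 (−10.95) and Slc4a1 (−12.00), fitted values over libraries partly without a count that are no bounds. With batch in place of the ID number they were −1.07, −1.69 and −4.75, with the replicate number as a block −1.26, −1.85 and −2.80, and with DESeq2 −1.66, −1.61 and −6.26, each with adjusted p = 1. MPP4 mutant 2 is the only library of its ID number, so the ID term absorbs it. Without it the differences were −10.94, −10.93 and −11.92, while the SE went from 1.90, 1.94 and 1.78 to 2.68, 2.62 and 2.0 and edgeR's adjusted p to 0.418, 0.418 and 0.0959. For Slc4a1 the unadjusted p was 9.05e-06 before and 8.68e-06 after, so its call ended through the adjustment over genes. Without the ID number of HSC mutant 1 the differences were −6.05, −5.94 and −9.05 (adjusted p = 1, 1 and 0.857), and without that of HSC control 3 they were −5.08, −5.18 and −6.66 (adjusted p = 1 for each). Slc4a1 was also lost without those of HSC control 2 (0.383), HSC mutant 3 (0.062) and HSC mutant 2 (0.0599).

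Lists whose mutant effect differed between MPP4 and HSC were lymphoid priming (median 0.34; camera adjusted p = 0.0201), erythroid (−3.50; 8.45e-11), S phase (−0.50; 4.04e-08), mitochondrial (0.20; 0.0288), B cell (2.89; 0.0288) and neutrophil genes (−6.99; 1.17e-06), each with adjusted p = 0.503 with an estimated correlation. Lymphoid priming had an adjusted p of 0.179 without the ID number of HSC mutant 3 and 0.887, with its direction turned, without that of HSC control 1 (range over alternatives 0.00175 to 0.903). S phase had 0.0711 without that of HSC control 1 (range 1.35e-13 to 0.503). Without the 5 libraries the adjusted p was 0.117 for erythroid (range 2.25e-17 to 0.503), 0.68 for lymphoid priming, 0.184 for mitochondrial (range 0.0023 to 0.544), 0.133 for B cell (range 0.00318 to 0.903) and 0.959 for neutrophil genes (range 8e-10 to 0.959). HSC control 1 held 39279 CPM of B cell transcripts, and without its ID number the B cell list had 0.762. That list also had 0.437, 0.194, 0.185 and 0.0638 without those of HSC control 2, HSC mutant 2, MPP4 mutant 2 and MPP4 control 2, the last 2 with a single library each that the ID term absorbs, and 0.83, with its direction turned, without that of HSC mutant 3. MPP4 mutant 2 and control 4 held 36564 and 4065 CPM of neutrophil transcripts, and the neutrophil list had 0.148 without the ID number of HSC control 3, which is also that of MPP4 control 4. Mitochondrial genes had 0.282, 0.179 and 0.0785 without those of HSC control 1, mutant 3 and mutant 1.

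Between MPP1 and HSC the lists that differed, each with its adjusted p and then the adjusted p with an estimated correlation, were stem cell identity (0.38; 0.00277 and 0.593), erythroid (−0.74; 0.00884 and 0.873), S phase (−0.69; 2.07e-13 and 0.317), mitochondrial (0.64; 0.00795 and 0.317) and neutrophil genes (−4.18; 2.42e-05 and 0.688). Stem cell identity had an adjusted p of 0.325 without the ID number of HSC control 3, 0.105 without that of HSC mutant 2 and 0.241 without the 5 libraries (range 6.24e-05 to 0.593). Without the 5 libraries the adjusted p was 0.905 each for erythroid genes (range 2.4e-05 to 0.905) and for neutrophil genes (range 1.15e-10 to 0.96), the latter with their direction turned. Neutrophil genes had 0.96 without the ID number of HSC control 3, also that of MPP1 control 2 with its 9364 CPM of neutrophil transcripts. Erythroid genes had 0.49, 0.138 and 0.14 without those of HSC control 3, mutant 2 and mutant 1, and mitochondrial genes 0.103, 0.247 and 0.0678 without those of HSC control 2, mutant 3 and mutant 2 (range 0.00632 to 0.317). Between MPP4 and MPP1, S phase genes differed (0.25; adjusted p = 0.0219, and adjusted p = 0.929 with an estimated correlation), with an adjusted p of 0.116, 0.183 and 0.371 without the ID numbers of HSC control 2, HSC control 3 and HSC mutant 3 (range 3.84e-06 to 0.929).

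Of 52 germline genes in the tables, 47 were under the count filter in every population. Of these, 32 had fewer than 10 counts over all libraries, with 43 counts in controls and 31 in mutants in all and none at all for 12 of them. Of the remaining 15, 11 had a higher and 4 a lower CPM in mutants than in controls over all libraries. The 95% counting interval in mutants lay above that in controls for 5 and below it for 0, and for 10 the intervals overlapped. Of the 5, Tex19.1 had 33 counts in 7 mutant libraries and Rhox5 12 counts in MPP4 mutant 4 alone, both with none in controls. Xlr3b had 25 counts in 7 mutant libraries and 2 in 2 controls, Syce1 63 in 9 mutant libraries and 21 in 2 controls, and Gpat2 27 in 7 mutant libraries and 7 in 5 controls. Of the 4 that were lower, Sycp1 had 14 counts in mutants and 33 in controls, Brdt 31 and 43, and Tex11 and Piwil2 5 and 15 each.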

How the results depend on the processing

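The term for the Xist level, the estimated correlation for differences between populations and the fits without the 2 or 5 libraries richest in transcripts of other cell types were chosen after the data were seen. Cases pool mutant effects and, where fitted, control comparisons. Called named genes kept direction and call in 61 of 61 cases each with RLE and no filter. They did in 27 of 27 with the stricter filter and 23 of 30 each with DESeq2 and limma-voom. With a shared spread it was 15 of 30 and without the batch term 8 of 21. With a library or ID number left out it was 350 of 424. Called lists kept theirs in 43 of 43 cases with RLE, 39 of 43 with no filter and 14 of 17 with the stricter filter. It was 256 of 305 with 1 left out (3 turned) and 7 of 43 with an estimated correlation. Over all alternatives, values of single genes held 151 lost calls, 17 gained calls and 25 reversals. Values of lists held 130, 11 and 14, with 553 on the same side, and 147 counts stayed within 1.5 times while 66 moved further. Of simulated 2-fold changes 43.2% were recovered in HSC, 22.1% in MPP1, 22.2% in MPP4 and 15% for MPP4 minus HSC. Power in the real data may be lower and was not tested. Leaving out an MPP1 library leaves a group with 1 library, which is assumed to vary like the others. Except where fewer libraries or genes were tested, the cause was not tested.

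In HSC, with no filter 83 genes rose and 29 fell (1.1e+02 in all, rounded), 9 passed with a shared spread, 5 without the batch term and 14 with DESeq2, and 13 (without mutant 2) to 83 (without mutant 3) with 1 library left out. Of the genes fixed by name 0 passed in edgeR, DESeq2 or limma-voom, with 2 at an unadjusted p under 0.05 in edgeR. Gata1 made it 1 with no filter and with the stricter filter, and the range was 0 to 1 with 1 library left out. Mpo turned to 1.31 without the batch term and 1.72 with limma-voom, and ran from −5.32 (without control 1) to 2.17 (without control 3). Of 7 lists 0 passed with an estimated correlation and 0 with fry, with 3 lists at an unadjusted p under 0.05 in each.

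In MPP1, 41 genes passed with no filter, 4 with a shared spread and 23 (without mutant 1) to 75 (without control 1) with 1 library left out. Lists that passed numbered 0 with an estimated correlation and 0 with fry, also at an unadjusted p under 0.05, and 2 (without mutant 1) to 12 (without mutant 2) with 1 library left out. Flt3 ran from −1.29 (without mutant 1) to 0.449 (without mutant 2), the ribosomal list's adjusted p from 3.43e-09 (without control 2) to 0.505 (without mutant 1) and the lymphoid list's from 0.315 (without mutant 2) to 0.697 (without mutant 1).

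In MPP4, 20 genes passed at an adjusted p under 0.1, 88 with no filter, 5 with the stricter filter, 17 with a shared spread, 3 without the batch term, 20 with the Xist term, 21 without control 4 and mutant 2, 28 with DESeq2, 13 with limma-voom and 1 (without control 3) to 20 (without control 2) with 1 library left out. Of the genes fixed by name 1 passed with no filter, Il7r. Lists numbered 12 with no filter, 3 with the stricter filter, 0 with an estimated correlation (4 at an unadjusted p under 0.05), 2 with fry and 4 (without control 3) to 9 (without control 4) with 1 library left out. Flt3 turned upward with RLE (0.00649), a shared spread (0.0116), no batch term (0.0332), batch C alone (0.329), the Xist term (0.0161), without control 4 and mutant 2 (0.0879), DESeq2 (0.00255) and limma-voom (0.000121), and ran from −0.128 (without control 4) to 0.205 (without mutant 2). Dntt was 0.596 without control 4 and mutant 2 and ran from −0.538 (without control 1) to 0.412 (without mutant 2), and Mecom from −0.165 (without mutant 3) to 0.404 (without mutant 1). The lymphoid list turned without control 4 and mutant 2 (adjusted p = 0.571), and its adjusted p ran from 0.0218 (without mutant 3) to 0.878 (without control 2).

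The difference between MPP4 and HSC called 18 genes with no filter, 0 with batch in place of the ID number, 1 with DESeq2, 9 without the 5 libraries and 0 (without the ID number of MPP4 mutant 2) to 10 (without that of HSC control 1) with an ID number left out. The adjusted p of its lymphoid list ran from 0.00178 (without HSC control 3's) to 0.887 (without HSC control 1's) and that of its B cell list from 0.00318 (without HSC control 3's) to 0.83 (without HSC mutant 3's). Its neutrophil list turned with batch in place of the ID number (adjusted p = 0.598), as did that of MPP1 minus HSC without the 5 libraries (adjusted p = 0.905). That between MPP1 and HSC called 2 genes with no filter, 1 in batch C alone and 2 without the 5 libraries. That between MPP4 and MPP1 called 8 without the 5 libraries and 0 (without HSC mutant 3's) to 4 (without HSC control 2's). Between controls, MPP4 against HSC gave 460 (without HSC control 2's) to 1158 genes (without HSC mutant 1's). MPP1 against HSC gave 71 with no filter, 3 with batch in place of the ID number and 16 (without HSC control 2's) to 40 (without HSC mutant 1's). There Slc4a1 ran from −2.73 (without HSC control 3's) to 7.74 (without HSC control 1's), and the lymphoid list turned in batch C alone (adjusted p = 0.204), with a range of 0.29 (without HSC control 1's) to 0.947 (without HSC control 3's).

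With the replicate number as a block, 40 genes passed in HSC: the 22 and 18 further ones. No pairing by number was seen in HSC beyond batch. Gata1 raised the count of fixed genes to 1 (adjusted p = 0.00741), and the lymphoid and megakaryocyte lists passed (adjusted p = 0.0435 each). Of the 22 genes and 7 lists called in HSC, 0 were lost with the block. In MPP1, where 2 libraries against 2 force the same value of 0.17 on both pairs, 43 genes passed with the block. In MPP4 the numbers do not pair (0.32, −0.02, 0.34 and −0.01), with 11 genes under the block, where Xlr4a (adjusted p = 0.0534) and the MHC class I list (adjusted p = 0.0634) no longer passed. For the difference between MPP4 and HSC the block left 0 genes, and erythroid (adjusted p = 0.264) and lymphoid genes (adjusted p = 0.429) did not pass and neutrophil genes turned (adjusted p = 0.631). For MPP1 minus HSC, mitochondrial genes did not pass (adjusted p = 0.0505).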

Other observations

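The tests over ID numbers and of X linkage were chosen after the data were seen.

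Antigen presentation and dendritic genes set MPP4 controls apart from HSC controls. Of 11 MHC class II genes 7 were higher in MPP4, among them H2-Aa (log2 difference 3.54, 1077 ± 453 CPM, n = 4, compared with 111.5 ± 73.0, n = 3), H2-Eb1 (4.48) and Ciita (2.79), which switches the class II genes on. Camera's adjusted p was 1.19e-10, and the adjusted p was 0.0681 with an estimated correlation. Of 14 dendritic genes 9 were higher, led by Flt3 (3.93, 476 ± 50.6 CPM compared with 30.4 ± 9.10), Clec9a (5.75) and Xcr1, which had no count in HSC controls (adjusted p = 9.66e-12, and adjusted p = 0.0709 with an estimated correlation). H2-Aa and H2-Ab1 belong to both lists. T cell genes Lck (2.16) and Trbc2 (3.17) were higher too, 2 of 6 (adjusted p = 0.00421, and adjusted p = 0.131 with an estimated correlation).

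Imprinted genes were lower in MPP4 than in HSC controls, 6 of 28 with 1 higher (median −0.45, adjusted p = 0.00104, and adjusted p = 0.0472 with an estimated correlation). They were led by the growth inhibitors Grb10 (−3.87, SE 0.30) and Cdkn1c (−2.51, SE 0.40), with Phlda2 (−3.76), Zrsr1 (−1.59) and Ndn (−1.58), while Igf2r was higher (1.01). Of 29 immediate-early genes 6 were lower in MPP4, among them Egr1 (26.1 ± 11.5 CPM, n = 4, compared with 115.7 ± 62.0, n = 3) and Dusp1 (−1.31). Btg2 was higher (1.76), but the list did not pass (adjusted p = 0.205). Of 19 neutrophil genes 5 were higher in MPP4 controls (adjusted p = 0.000228, and adjusted p = 0.451 with an estimated correlation). In MPP1 controls 2 were higher (adjusted p = 1.8e-11, and adjusted p = 0.382 with an estimated correlation). MPP4 control 4 and MPP1 control 2 held most neutrophil transcripts among these controls. In MPP1 controls immediate-early (median −0.23) and ribosomal genes (median −0.11) were lower than in HSC, each with adjusted p = 0.0417, and with adjusted p = 0.639 and 0.788 with an estimated correlation.

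A hypothesis was that the level of genes under control of DNA methylation separates the 4 mutant from the 4 control ID numbers. Germline genes differed by 1.51 (log2 of the summed CPM) and 1.98 (mean log2 CPM), each with an exact two-sided permutation p = 0.0286, the smallest possible, and 0.0381 adjusted over 8 tests, which is consistent with that hypothesis. These permutations ignore batch, and within batches the exact p was 0.0833, the smallest that 24 arrangements can give. For imprinted genes the answer turned with the measure. They differed by −0.46 in the summed CPM (exact permutation p = 0.0286, and 0.0833 within batches) and by −0.28 in the mean log2 CPM, where the ID numbers overlapped (exact permutation p = 0.114, and 0.25 within batches). The list had a median of −0.06 in MPP1, where it did not pass, so the hypothesis stays open for it. G2/M genes differed by 0.27 in the summed CPM (exact permutation p = 0.0857) and by 0.44 in the mean log2 CPM (0.0286), with 0.0833 within batches for both.

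A second hypothesis was that X-linked genes are over-represented among the genes that rose. Of 34 genes that rose in any population 4 were X-linked, compared with 320 of 9914 tested (odds ratio 4.03, Fisher's exact two-sided p = 0.023). Of the 4, 3 were Xlr genes, which share much of their sequence and are not independent. With the Xlr genes counted as 1, 2 of 32 were X-linked, compared with 318 of 9912 (odds ratio 2.02, Fisher's exact two-sided p = 0.274), so the hypothesis stays open.

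Lists that did not pass between mutants and controls are given with camera's adjusted p. In HSC these were myeloid progenitor (0.362), megakaryocyte (0.0712, and 0.0435 with the replicate number as a block), interferon (0.111), MHC class I (0.469) and class II genes (0.132), p53 targets (0.178), apoptosis regulators (0.657), the DNA methylation machinery (0.518), NF-kB (0.164), mitochondrial (0.132), dendritic (0.0827), endothelial or stromal (0.469) and sex-linked genes (0.662). In MPP1 they were stem cell identity (0.104), lymphoid priming (0.526), megakaryocyte (0.114), erythroid (0.174), imprinted (0.881), interferon (0.295) and MHC class I genes (0.107), apoptosis regulators (0.734), the methylation machinery (0.211), NF-kB (0.505), mitochondrial (0.107), neutrophil (0.0533), dendritic (0.377), endothelial or stromal (0.506) and sex-linked genes (0.779).

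In MPP4 they were stem cell identity (0.677), myeloid progenitor (0.0885), megakaryocyte (0.922), erythroid (0.922), imprinted (0.421), interferon (0.565), MHC class II (0.102) and S phase genes (0.43), p53 targets (0.522), apoptosis regulators (0.677), the methylation machinery (0.677), NF-kB (0.38), mitochondrial (0.922), neutrophil (0.38), monocyte (0.522), dendritic (0.922), endothelial or stromal (0.852) and sex-linked genes (0.922). Median, mean and test differed in sign for MPP4 erythroid (−0.12, −0.97, higher), megakaryocyte (0.02, −0.11, lower) and dendritic genes (0.06, 0.10, lower) and for HSC sex-linked genes (0.24, −0.21, higher). Too few members were tested for camera among T cell genes (3, 3 and 3 in HSC, MPP1 and MPP4), B cell genes (2, 2 and 4), NK cell genes (1, 1 and 2), neutrophil genes in HSC (3), monocyte genes in HSC and MPP1 (4 and 3) and MHC class II genes in MPP1 (4), and no mast cell, basophil or eosinophil gene was tested.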
